A study of Gallus gallus with 36 samples.

How the data were processed

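RNA of chicken pineal glands and retinas was sequenced at 6 circadian times in constant darkness, with 3 libraries per tissue and time, 36 in all. Per the labels' protocols, RNA was extracted with TRIzol and RNeasy columns and made into standard Illumina libraries. The submitters' processing notes name Trimmomatic, TopHat and Cufflinks without versions or roles. The genome build is not given in the sources used here, so coordinates are printed as the deposited tables give them. The deposited estimated counts per Ensembl transcript, which the authors made from the reads, need not be whole: 68.1% of the values are whole, and 95.0% of the totals per gene are whole within 0.01. The authors also deposited FPKM values, which divide by transcript length and library size, for the same transcripts and libraries, used here only as an alternative. Both tables hold 23352 transcripts of 17934 Ensembl genes, 14049 of which have a single transcript, and no cell was 0 in one table and not in the other. Of the transcripts 1570 are at 0 in every library and 4423 have no Ensembl gene name. Of 4207 transcripts with a RefSeq identifier, 3935 were matched to a table of RefSeq gene names, which named 255 more. Because counts were split between transcripts of a gene by estimation, values are for transcripts, and those of close paralogs, such as ribosomal proteins, haemoglobins and crystallins, are uncertain. Whether strand was used in counting is not given in the sources used here, so overlapping antisense genes are not told apart.

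Libraries were assigned to tissue, time and replicate from their labels. The estimated counts were rounded to whole numbers and analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3, and plots were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Within each tissue, TMM scaling and filterByExpr by circadian time were used. Rhythm was tested with edgeR's quasi-likelihood F test of the cosine and sine of a 24 h curve (2 coefficients). Night (CT16 and CT20) was set against day (CT4 and CT8) in a model with a mean per time. A difference in rhythm between tissues was tested as the interaction of tissue with the cosine and sine over all 36 libraries, and the tissues were compared in a model with a mean per tissue and time. P-values were adjusted by Benjamini-Hochberg over all tested transcripts with a threshold of 0.05. The SE of a difference is its size over the square root of F. Amplitude and peak come from a least-squares 24 h curve on log2 CPM (prior count 2), with SEs from the delta method. Calls in both tissues were compared with Fisher's exact test, one-sided. A fold against a tissue at 0 is a lower bound set with 3 counts over its 18 libraries. Intervals of low-count ratios are 95% exact (Clopper-Pearson) and, like the floors, cover counting error only.

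Before the data were examined, 34 gene lists, the tests, the rule for naming genes and all alternatives but 1 were fixed. The lists cover clock activators, clock repressors, clock output bZIP factors and kinases, the melatonin pathway, adrenergic and cyclic AMP signalling, rod and cone phototransduction, non-visual opsins, retinal pigment epithelium and visual cycle, photoreceptor and pineal transcription factors, bipolar, amacrine and horizontal, and ganglion cells, Müller glia, myelin, choroid plexus and ependyma, lymphocytes, macrophages, blood cells, endothelium, fibroblasts, lens, striated muscle, immediate early genes, heat shock, unfolded protein response, glycolysis, cholesterol synthesis, neurosteroid synthesis, dopamine, cell division, mitochondrially encoded genes, ribosomal proteins and the W chromosome. Lists with at least 5 tested members were tested with camera (preset correlation 0.01), and again with an estimated correlation. Of the lists tested, 13 of 31 were called for pineal night against day, 8 of 29 for the retina and 20 of 32 between tissues, and 3, 0 and 6 held with an estimated correlation. For a symbol with several transcripts, the most counted stands for it. Named are all clock members and 5 melatonin genes, the 10 largest amplitudes per tissue (mean of at least 1 CPM), up to 4 called members of each other list by smallest p, the 10 largest folds per tissue (at least 10 CPM, all 18 libraries above the other 18) and the 10 smallest p of the rhythm difference. Names that are only placeholders for an identifier were passed over. A few genes that the rule takes in are not reported here. The GAD67, KCNJ13, FOLR1, CLIC6 and other levels per library that lie outside this rule were chosen after their values were seen. Some genes are in more than 1 list. TTR is in the choroid plexus and visual cycle lists, and OTX2 in the choroid plexus and transcription factor lists. RLBP1 is in the visual cycle and Müller glia lists, TH in the amacrine and dopamine lists and NR4A2 in the immediate early and dopamine lists.

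Replicates were compared before use: the 36 pairs of libraries of 1 group had chi-square values per degree of freedom between 4.64 and 29.9, so none was a repeat within sampling noise. Mitochondrial transcripts took 4.32 to 5.57% of the counts in pineal and 3.52 to 4.26% in retina libraries. The alternatives were size factors in place of TMM, DESeq2, no filter, the replicate number as a block, transcripts summed per symbol, limma on log2 FPKM with pseudocounts of 0.1 and 1 (mean FPKM of at least 0.5) and without a filter, time as a 6-level factor, both tissues in 1 fit, CT12 counted as night and CT0 as day, an estimated correlation, and leaving out each library. Fits were tested on simulated counts with 200 changed transcripts picked at random, with each comparison simulated a single time. The rhythm test found 40.3, 62.7 and 81.8% of pineal changes of amplitude 0.25, 0.5 and 1 (15846 transcripts). Of retina ones it found 35.8, 70.1 and 87.9% (14760 transcripts), so many small simulated rhythms were missed. More transcripts were called rhythmic in the data, which changes the p-value that the adjustment requires, so these shares need not hold there. False calls made up 7.5% of the pineal and 3.7% of the retina rhythm calls. The night test found 34 and 77% of pineal differences of 0.5 and 1 (15868 transcripts, 5.1% false) and 58 and 75% of retina ones (14757 transcripts, 2.9% false). The rhythm difference test found 59 and 74% (16647 transcripts, 7.6% false), and the tissue test 37.3, 67.2 and 90.9% at 0.25, 0.5 and 1 (16453 transcripts, 2.3% false). Shares over the 5% aimed at are those of pineal rhythm, pineal night and the rhythm difference.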

Results

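The study measured RNA from the pineal gland and the retina of chickens to find transcripts whose level follows the time of day. The pineal gland of birds holds its own photoreceptors and circadian clock and makes melatonin at night, and the retina holds a clock too. Birds lived for 9 days in 12 h of light and 12 h of darkness and then in constant darkness on day 10, when tissue was taken at circadian time (CT) 0, 4, 8, 12, 16 and 20, CT0 being the time at which lights would have come on. Each library held RNA of 3 pooled pineal glands or of 1 retina, and each tissue and time had 3 libraries, which makes 36 libraries in 12 groups over a single cycle. Total counts per library ran from 6583163 to 9434608 in the pineal gland and from 4994388 to 8122277 in the retina. Each pineal library had counts in 18538 to 18984 of the 23352 transcripts, and each retina library in 17783 to 18237. The 10 transcripts with most counts took 9.1 to 14.2% of a pineal library and 4.2 to 4.7% of a retina library. Nothing beyond the labels says whether the libraries of a group came from separate birds, so p-values measure only the spread between these samples, which may be technical. Levels are CPM, each library's counts scaled to a common total, as mean ± SD (n = 3 libraries per time), amplitudes are the distance from the mean to the peak of a fitted 24 h curve in log2 units ± SE, and night minus day is the log2 difference of CT16 and CT20 from CT4 and CT8 ± SE. Adjusted p-values are from edgeR's quasi-likelihood tests with Benjamini-Hochberg adjustment unless camera, a test of gene lists, is named.

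The first comparison asked which pineal transcripts followed a 24 h curve in constant darkness. Among transcripts with a symbol and a mean of at least 1 CPM, the largest amplitude was that of G0S2 (ENSGALT00000040292, chromosome 26, 2961681 to 2961980), an inhibitor of triglyceride breakdown, whose level was 62.1 ± 7.42 CPM at CT16 and 0.686 ± 0.157 CPM at CT0, a fitted 86.5-fold range. Clock genes were among the strongest: PER3 had a fitted peak-to-trough ratio of 26, PER2 of 12.5 and ARNTL of 11.3. PPEF2, a calcium-binding phosphatase of photoreceptors, rose from 13.2 ± 2.05 CPM at CT0 to 234 ± 27.9 CPM at CT12. Every tested member of the cholesterol synthesis list and most tested members of the clock, melatonin, cone, heat shock and unfolded protein lists were rhythmic. Of 16070 tested transcripts, 3393 (21.1%) passed an adjusted p of 0.05, and 2901 gene symbols were among them. Their median peak-to-trough ratio was 1.43 (quartiles 1.25 to 1.82), 635 reached 2-fold and 117 reached 4-fold. Fitted peaks gathered around CT4 (731 transcripts), CT12 (703) and CT16 (864), with 461 nearest CT0, 263 nearest CT8 and 371 nearest CT20. After G0S2 and PER3, the largest amplitudes among transcripts with a symbol were those of CPNE7 (2.59 ± 0.30, peak at CT3.12), the laminin subunit LAMB3 (2.36 ± 0.19, CT16.99), SPINK5 (2.24 ± 0.50, CT18.6), DOCK4 (2.18 ± 0.47, CT14.96), PPEF2 (2.12 ± 0.09, CT12.43) and TMC3 (1.73 ± 0.22, CT16.34). CPNE7 fell to 0.217 ± 0.377 CPM at CT16, so its trough lay near the limit of detection. Over the single cycle sampled, a straight line through the 6 times fitted 652 of the 3393 better than the 24 h curve did.

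**Figure D1:**
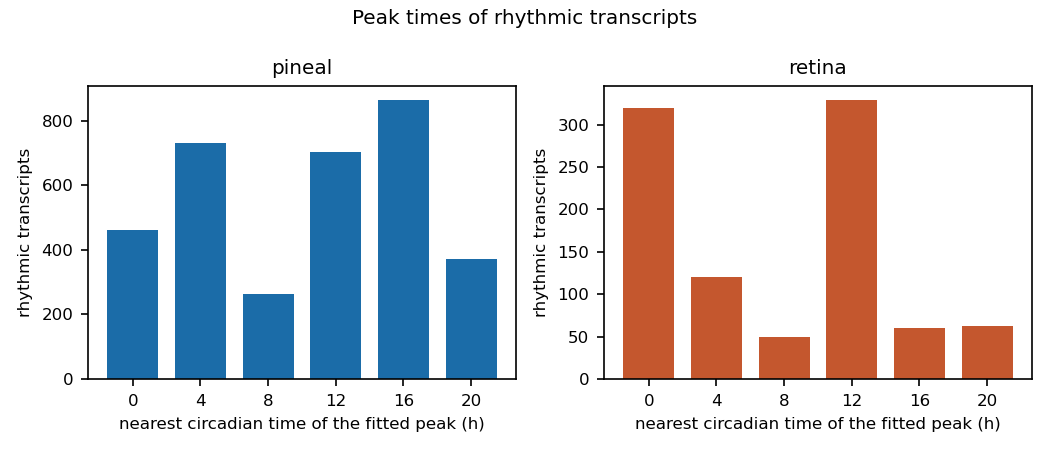
Number of rhythmic transcripts whose fitted peak lies nearest each circadian time, pineal gland and retina, as bars from 0. Pineal peaks gather at CT4, CT12 and CT16 (731, 703 and 864 transcripts), retina peaks at CT0 and CT12 (320 and 329).

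Night was then set against day in the pineal gland. This contrast leaves out CT0 and CT12, and it cancels out for a 24 h curve that peaks at either time. G0S2 rose at night by 3.97 ± 0.12, LAMB3 rose by 5.04 ± 0.55, TMC3 by 2.91 ± 0.24 and AANAT, the enzyme that times melatonin synthesis, by 1.58 ± 0.07. PER2 fell by 2.36 ± 0.10 and CPNE7 fell by 3.81 ± 0.50. In each of these 6 transcripts all 6 night libraries lay beyond all 6 day libraries in that direction. For a transcript and direction chosen beforehand chance gives this in 0.108% of cases. Most of these were named for a large amplitude in the same libraries, so that share does not apply to them. Counts such as 5 of 6 libraries likewise give the night libraries that lay beyond all 6 day libraries. In all, 1343 transcripts (8.4%) were higher and 1070 (6.7%) lower at night, and 2111 of these were also called rhythmic. The share of calls that were higher at night was 55.7%, 54.6% with size factors and 54.1% with DESeq2 on the same counts. It was between 43.2 and 43.8% with limma on log2 FPKM, which changes values, scaling, filter and test at once, and which of these moved it was not tested.

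Clock genes in the pineal gland ran in opposite phases, the activators peaking in the early night and most repressors around dawn. Of the activators, 4 of 6 tested were rhythmic (4 adjusted over the list alone) with a mean peak at CT13.52. ARNTL went from 13.4 ± 3.24 CPM at CT0 to 137 ± 0.972 CPM at CT12, CLOCK from 41.7 ± 4.71 to 88.2 ± 4.8 CPM at the same times, NPAS2 had an amplitude of 1.40 ± 0.18 and ARNTL2 of 0.92 ± 0.04. RORA (0.04 ± 0.08, edgeR adjusted p = 0.925) and RORB (0.12 ± 0.05, edgeR adjusted p = 0.138) did not pass. All 7 tested repressors were rhythmic (7 adjusted over the list alone). PER3 (ENSGALT00000000797, chromosome 21, 265014 to 280881) peaked at CT1.14 ± 0.13 h, with 298 ± 23.5 CPM at CT0 against 14.5 ± 1.83 CPM at CT12 (edgeR adjusted p = 2.6e-12), and PER2 peaked at CT3.25, CRY4 at CT3.22, BHLHE40 at CT1.02, CRY2 at CT0.13 and NR1D2, a repressor of ARNTL, at CT22.75. CRY1 stood apart with its peak at CT10.58 ± 0.14 h and 268 ± 12.8 CPM at CT12. At night 4 activators were higher and none lower, with a list median of 0.40 (camera adjusted p = 1.1e-04; adjusted p = 0.0451 with an estimated correlation). Of the repressors 5 were lower and NR1D2 was higher, with a median of -0.64 (camera adjusted p = 4.7e-06; adjusted p = 0.0352 with an estimated correlation). Of the clock output and kinase list, 5 of 8 were rhythmic (5 adjusted over the list alone): the activator HLF peaked at CT0.84 and its rival NFIL3, which binds the same sites, at CT12.32 with 62.6 ± 2.6 CPM at CT12 and 10.6 ± 1.68 CPM at CT20. FBXL21, which acts on cryptochrome stability, peaked at CT14.77. CSNK1E also passed (amplitude 0.34 ± 0.11, edgeR adjusted p = 0.0469). That call ended without any 1 of 12 of the 18 libraries (edgeR adjusted p = 0.0507 to 0.107), without 3 libraries low in TTR, named below (0.155) and without the filter (0.0518). It also ended with the replicate number as a block (edgeR adjusted p = 0.0666), with time as a 6-level factor (0.221), with both tissues in 1 fit (0.326) and with limma on log2 FPKM (limma adjusted p = 0.0672 to 0.0882). The most counted transcripts of TEF, CSNK1D and GSK3B did not pass (amplitudes 0.14, 0.07 and 0.04), although a less counted TEF transcript did (0.42 ± 0.06). At night 2 of this list were higher and 1 lower (camera adjusted p = 0.183, median 0.12).

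**Figure D2:**
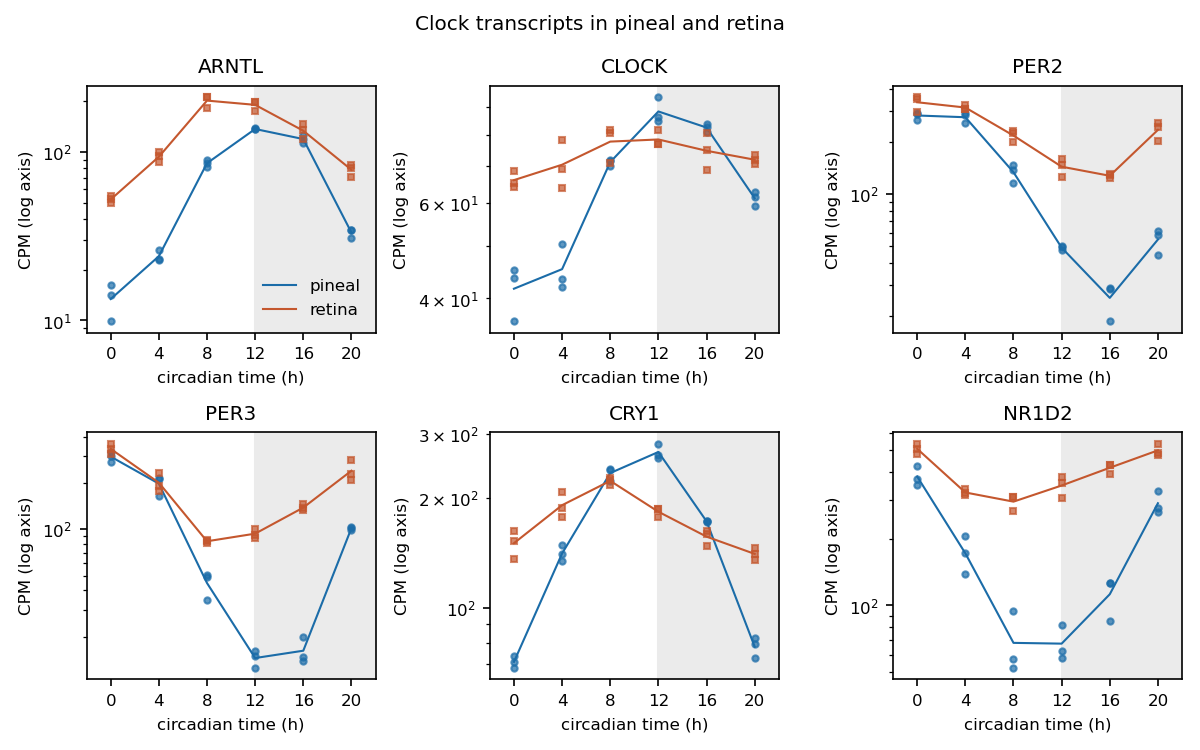
Levels of 6 clock genes (CPM, log axis) by circadian time; points are single libraries (circles pineal gland, squares retina), lines join the means of 3 libraries and grey marks CT12 onward. Pineal ARNTL goes from 13.4 CPM at CT0 to 137 CPM at CT12 and PER3 from 298 to 14.5 CPM.

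The enzymes that turn tryptophan into melatonin were all rhythmic in the pineal gland, and 3 of the 4 peaked at night. TPH1 (ENSGALT00000010084, chromosome 5, 13546070 to 13556611), which makes the first step, went from 6808 ± 1049 CPM at CT0 to 28184 ± 2646 CPM at CT12, and DDC from 181 ± 14.5 to 911 ± 62.6 CPM at CT16. AANAT (ENSGALT00000003024, chromosome 18, 4365296 to 4369121) was lowest at CT4 (339 ± 41.2 CPM) and highest at CT20 (1411 ± 101 CPM). ASMT, the last enzyme, ran the other way, with 3641 ± 415 CPM at CT0 and 1754 ± 73.5 CPM at CT16. AANAT rose at night by 1.58 ± 0.07 in 6 of 6 libraries (edgeR adjusted p = 2.5e-09), DDC by 0.87 ± 0.05 in 6 of 6 and TPH1 by 0.91 ± 0.09 in 5 of 6, while ASMT fell by 0.77 ± 0.08 in 6 of 6. Of the melatonin list 8 of 10 tested members were rhythmic (8 adjusted over the list alone), including the cofactor enzyme GCH1 with its peak at CT13.01 and PTS and SPR with smaller amplitudes (0.30 and 0.23). At night 5 members were higher and 1 lower (6 and 1 adjusted over the list alone). The list as a whole was higher, with a median of 0.26 (camera adjusted p = 1.9e-04), a call that was lost at adjusted p = 0.165 with an estimated correlation. The melatonin receptor gene MEL1A had too few pineal counts to be tested.

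**Figure D3:**
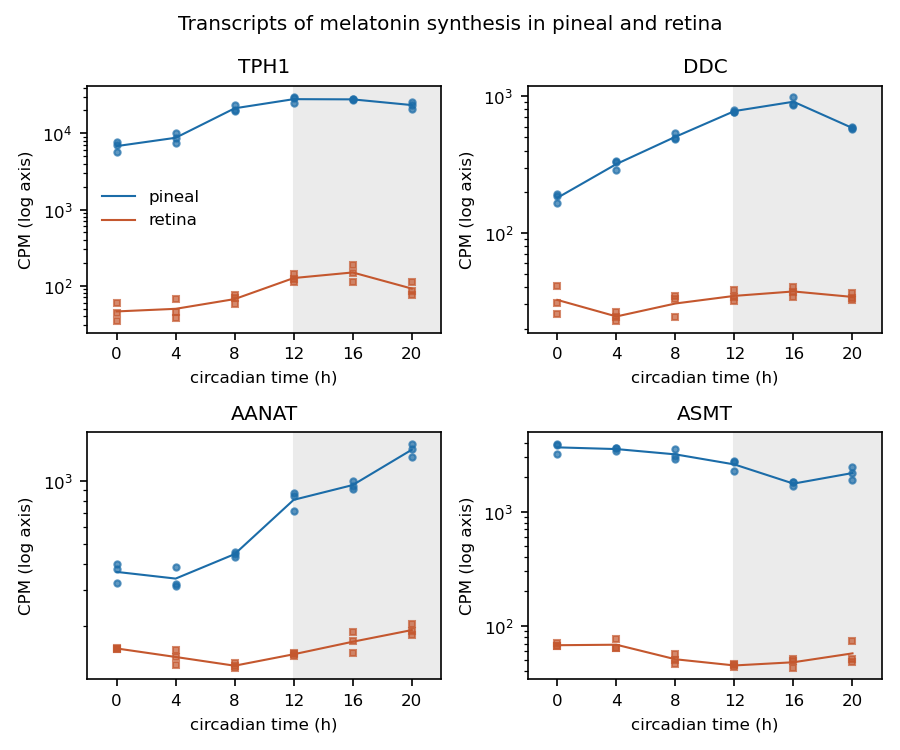
Levels of TPH1, DDC, AANAT and ASMT (CPM, log axis) by circadian time in the pineal gland (circles) and retina (squares); points are single libraries and lines join the means of 3. In the pineal gland TPH1, DDC and AANAT are highest between CT12 and CT20, ASMT at CT0.

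Genes of light detection were also rhythmic in the pineal gland, at widely spread times. GNB3 (ENSGALT00000023410, chromosome 1, 80401456 to 80410938), the cone transducin beta subunit, rose from 41.8 ± 2.75 CPM at CT4 to 294 ± 23.6 CPM at CT16 and was higher at night by 2.64 ± 0.10 in 6 of 6 libraries (edgeR adjusted p = 4.1e-10). CNGB3, a cone channel subunit, moved the other way, with 110 ± 1.46 CPM at CT8 and 33.1 ± 3.02 CPM at CT16. Of the cone list 8 of 9 tested members were rhythmic (9 adjusted over the list alone), among them PDE6C with its peak at CT20.15 and ARR3 at CT0.64, and 2 were higher and 2 lower at night. Of the rod list 5 of 11 were rhythmic (5 adjusted over the list alone), PDE6B peaking at CT1.57 and the channel subunits CNGA1 and CNGB1 at CT12.18 and CT13.41, and 2 were higher and 1 lower at night. Of the non-visual opsins 5 of 6 were rhythmic (5 adjusted over the list alone): pinopsin, OPNP, was lowest at CT0 (369 ± 51.3 CPM) and highest at CT12, with a fitted peak-to-trough ratio of 1.87, melanopsin, OPN4, peaked at CT11.22, and RGR peaked at CT6.99 and fell at night by 0.51 ± 0.05. In all, 2 opsins were higher, RRH and OPN4-1, and 2 lower at night. The RRH call ended without any 1 of 13 libraries (edgeR adjusted p = 0.0502 to 0.120), without the 3 low in TTR (0.0868), without the filter (0.0546), with the replicate number as a block (0.0630), with both tissues in 1 fit (0.121) and with limma on log2 FPKM (limma adjusted p = 0.0808 to 0.0980). The OPN4-1 call ended without any 1 of 3 libraries (edgeR adjusted p = 0.0589 to 0.0617) and with limma on log2 FPKM of all transcripts (limma adjusted p = 0.0641). OPNP was lower at night by 0.24 ± 0.07, but not with CT12 counted as night, and the call also ended with both tissues in 1 fit (edgeR adjusted p = 0.0557) and without any 1 of 9 of the 12 day and night libraries (edgeR adjusted p = 0.0586 to 0.0918). Of the pigment epithelium and visual cycle list 7 of 14 were rhythmic (7 adjusted over the list alone), with BEST1 peaking at CT17.38 and RBP3 at CT21.45, and 4 were higher and 2 lower at night. With both tissues in 1 fit the night calls of STRA6 (edgeR adjusted p = 0.108), RPE65 (0.0665) and GNB1 of the rod list (0.0625) ended, and with CT12 as night and CT0 as day those of RPE65 (0.195), RBP3 (0.427) and SLC24A2 of the cone list (0.290). None of these lists passed camera (adjusted p = 0.933 for cone, 0.509 for rod, 0.314 for opsins and 0.509 for visual cycle; medians -0.07, 0.09, -0.25 and -0.05). Of the transcription factors of photoreceptors and pinealocytes 7 of 9 were rhythmic (7 adjusted over the list alone), with a mean peak at CT15.96. At night 7 were higher (8 adjusted over the list alone). LIM3 rose at night by 0.80 ± 0.08, NEUROD4 by 0.56 ± 0.07 and OTX2 by 0.25 ± 0.05. The list median was 0.24 (camera adjusted p = 3.7e-06; adjusted p = 0.0646 with an estimated correlation, which ends the call).

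Most members of the 2 chaperone lists were lower in the pineal gland at night than by day, and sterol synthesis peaked at dusk. Of the unfolded protein response, the set of endoplasmic reticulum chaperones and their regulators, 13 of 14 members were rhythmic (13 adjusted over the list alone), with a mean peak at CT4.78. At night 12 were lower and none higher, with a median of -0.37 (camera adjusted p = 1.8e-13; adjusted p = 0.0451 with an estimated correlation). HSPA5 went from 1091 ± 59.5 CPM at CT0 to 515 ± 48.3 CPM at CT16 and HSP90B1 fell by 0.48 ± 0.04 in 6 of 6 night libraries. Of the heat shock and cold inducible list 11 of 13 were rhythmic (11 adjusted over the list alone) and 10 were lower at night, such as HSPH1 with 454 ± 29.6 CPM at CT0 and 184 ± 8.86 CPM at CT16. The cold-inducible CIRBP peaked at CT13.76. The list median was -0.21 (camera adjusted p = 2.6e-05; adjusted p = 0.264 with an estimated correlation, which ends the call). Of glycolysis 8 of 15 were rhythmic (8 adjusted over the list alone), and 6 were lower and 2 higher at night (7 and 2 adjusted over the list alone): GAPDH fell by 0.59 ± 0.04 and PKM2 by 0.46 ± 0.05, and LDHA rose by 0.33 ± 0.05 and ENO2 by 1.11 ± 0.20. The median was -0.12 while the mean was 0.03 (camera adjusted p = 0.00515; adjusted p = 0.458 with an estimated correlation, which ends the call). All 16 cholesterol synthesis genes were rhythmic (16 adjusted over the list alone), with a mean peak at CT12.85. SC4MOL reached 342 ± 25.5 CPM at CT12 against 141 ± 4.11 CPM at CT4, and CYP51A1 128 ± 9.23 CPM at CT12 against 49.9 ± 5.68 CPM at CT0. At night 5 were higher and none lower (6 and 0 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.0375; adjusted p = 0.598 with an estimated correlation, which ends the call), and the MVD call ended without any 1 of 5 libraries (edgeR adjusted p = 0.0555 to 0.0738).

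In the remaining pineal lists the share of rhythmic members ran from 0 to 50%, against 21.1% of all tested transcripts. Of cell division genes 6 of 17 were rhythmic (7 adjusted over the list alone): the replication factors MCM2 and MCM3 fell at night by 0.53 ± 0.08 and 0.62 ± 0.05, and TOP2A rose by 0.48 ± 0.08. Of 64 cytosolic ribosomal proteins 2 were rhythmic (0 adjusted over the list alone), and their median of -0.08 passed as a list (camera adjusted p = 5.9e-05; adjusted p = 0.642 with an estimated correlation, which ends the call). Of amacrine and horizontal cell markers 2 of 9 were rhythmic (2 adjusted over the list alone), the glycine transporter SLC6A9 and PROX1, and both were higher at night. The list median was 0.73 (camera adjusted p = 0.0111; adjusted p = 0.465 with an estimated correlation, which ends the call). Its member GAD67 was at 35.1 CPM in CT20 replicate 1, 21.2 CPM in CT12 replicate 1 and 21.8 CPM in CT0 replicate 2, and between 2.4 and 8.5 CPM in the other 15 libraries. Lymphocyte markers had 1 of 14 rhythmic, CXCR4, lower at night by 0.81 ± 0.09 in 6 of 6 libraries, and macrophage markers 0 of 8. Their list medians were -0.48 and -0.34 (camera adjusted p = 0.00515 and 0.00962; adjusted p = 0.571 and 0.565 with an estimated correlation, which ends both calls). Of lens markers 2 of 5 were rhythmic, CRYAB and CRYBA1, which fell at night by 1.08 ± 0.18 and 0.89 ± 0.13, with a list median of -0.41 (camera adjusted p = 0.0371; adjusted p = 0.264 with an estimated correlation, which ends the call). Rhythmic counts in the other lists were 5 of 18 for adrenergic and cyclic AMP signalling (2 higher and 2 lower at night, ADRA2C lower by 0.52 ± 0.06), 3 of 7 immediate early, 4 of 11 endothelium and pericytes, 2 of 7 neurosteroid synthesis, 2 of 4 dopamine, 2 of 8 ganglion cell, 1 of 6 bipolar cell, 1 of 10 Müller glia, 1 of 5 striated muscle and 0 of 6 myelin, 4 blood cell, 8 fibroblast and 12 mitochondrially encoded members. Adjusted over the list alone, adrenergic had 6 and endothelium 5, and the rest kept their counts. Among these lists the rhythms of TNNC2, RPL14, RPS10, FOXJ1, FLT1, RGS5, ESAM, EGR1, DUSP1, NR4A3, AKR1D1 and DRD4 were each not called under at least 1 alternative or without 1 library, and likewise the night differences of VIPR1, ADCY8, C1QC, LUM, TNNC2, FLT1, EGR1, DUSP1, AKR1D1, CDC2 and RPS10. With the replicate number as a block TNNC2 (edgeR adjusted p = 0.0561) was not called rhythmic, nor VIPR1 (0.0526) and C1QC (0.0520) different at night. Of choroid plexus and ependyma markers 3 of 9 were rhythmic and 2 rose at night: AQP1 by 0.68 ± 0.09, and OTX2, which is also in the transcription factor list. The choroid plexus list had a median of -0.41 and a mean of -0.23 (camera adjusted p = 0.933). The carrier TTR, the most abundant choroid plexus gene, was at 982 CPM in CT12 replicate 1, 1336 CPM in CT12 replicate 3 and 1512 CPM in CT20 replicate 1, and between 23013 and 43683 CPM in the other 15 pineal libraries. KCNJ13, FOLR1, CLIC6 and KL were likewise lower in those 3 than in all of the other 15. Without the 3, a choice made after their values were seen, 2991 transcripts were rhythmic, 1139 higher and 896 lower at night, and camera called 11 lists in place of 13.

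**Figure D4:**
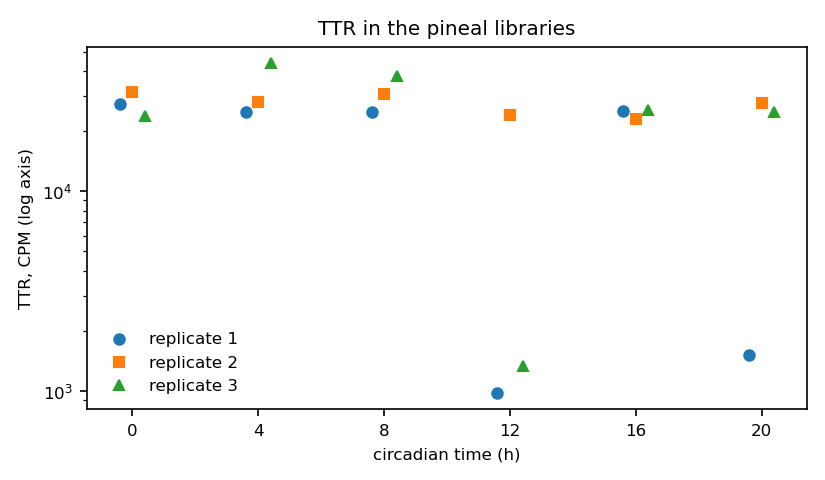
TTR level (CPM, log axis) in each of the 18 pineal libraries by circadian time, with the marker showing the replicate. The 2 low points at CT12 and the 1 at CT20 lie between 982 and 1512 CPM, the other 15 between 23013 and 43683 CPM.

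In the retina fewer transcripts passed the same test. The largest amplitude was that of a transcript named RBP4 in the deposited table (ENSGALT00000024805, chromosome Z, 52408730 to 52414029), with 3731 ± 212 CPM at CT0 and 245 ± 39.9 CPM at CT12, a fitted 16.7-fold range. RDH8, a retinol dehydrogenase, went from 184 ± 42.2 CPM at CT4 to 22.2 ± 3.55 CPM at CT16, NR2E3, a photoreceptor nuclear receptor, from 74.1 ± 31.4 CPM at CT0 to 7.08 ± 1.34 CPM at CT12, and the rod phosphodiesterase subunit PDE6B from 251 ± 67.5 to 40.3 ± 10.2 CPM at the same times. Of 14956 tested transcripts 941 (6.3%) were rhythmic, with 836 gene symbols. Their median peak-to-trough ratio was 1.32 (quartiles 1.20 to 1.55), 106 reached 2-fold and 20 reached 4-fold. Peaks gathered around CT0 (320) and CT12 (329), with 120 nearest CT4, 50 nearest CT8, 60 nearest CT16 and 62 nearest CT20. The remaining large amplitudes were those of MYCL1 (1.37 ± 0.12, peak at CT12.16), BLIMP-1, a repressor active in photoreceptor precursors (1.13 ± 0.08, CT10.23), PER3, PPEF2 (0.97 ± 0.08, CT10.92), PDE6G (0.97 ± 0.14, CT17.75) and ARNTL. A straight line fitted 26 of the 941 better than the 24 h curve. Tested with time as a 6-level factor, 515 were called.

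In the retina clock activators and repressors again peaked apart, with CRY1 and RORA as exceptions, and their rhythmic members other than RORA had smaller amplitudes than in the pineal gland. ARNTL went from 52.3 ± 2.45 CPM at CT0 to 202 ± 16.1 CPM at CT8 (peak CT11.0) and PER3 from 83.6 ± 1.85 CPM at CT8 to 334 ± 26 CPM at CT0 (peak CT22.91). Of the activators 4 of 6 were rhythmic (5 adjusted over the list alone): ARNTL, NPAS2, ARNTL2 and RORA, the last with an amplitude of 0.21 ± 0.04 that was not called when both tissues were fitted together. CLOCK (0.12 ± 0.03, edgeR adjusted p = 0.0756) and RORB (0.07 ± 0.03, edgeR adjusted p = 0.461) did not pass. Of the repressors 6 of 7 were rhythmic (6 adjusted over the list alone), with a mean peak at CT23.05: PER2 peaked at CT1.9, BHLHE40 at CT21.98, CRY2 at CT21.22, NR1D2 at CT20.51 and CRY1 at CT8.00, and CRY4 (0.11 ± 0.06, edgeR adjusted p = 0.533) did not pass. Of the output list 3 of 8 were rhythmic (3 adjusted over the list alone), HLF at CT23.65, NFIL3 at CT10.43 and FBXL21 at CT10.99. The transcripts of TEF, CSNK1D, CSNK1E and GSK3B had amplitudes of 0.01, 0.02, 0.37 and 0.06 and did not pass. Of the melatonin list 3 of 12 were rhythmic (5 adjusted over the list alone). TPH1 rose from 45.8 ± 13 CPM at CT0 to 149 ± 36.6 CPM at CT16, AANAT from 130 ± 3.61 CPM at CT8 to 192 ± 11.2 CPM at CT20, and ASMT peaked at CT1.3. DDC (0.25 ± 0.07, edgeR adjusted p = 0.102) and MEL1A (0.25, edgeR adjusted p = 0.343) did not pass. The AANAT rhythm, too, was lost in the fit of both tissues together.

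Phototransduction genes were rhythmic in nearly all tested members of the cone list and most of the rod list in the retina. Of the cone list 9 of 10 were rhythmic (10 adjusted over the list alone) and of the rod list 9 of 13 (10 adjusted over the list alone). Of these 18, 11 peaked between CT22.63 and CT1.61. ARR3, the cone arrestin, went from 500 ± 30.9 CPM at CT12 to 1484 ± 138 CPM at CT0 (amplitude 0.82 ± 0.03, edgeR adjusted p = 1.5e-11), and GUCA1A, CNGA3, GRK7, RGS9 and PDE6B peaked at CT1.26, CT0.33, CT0.90, CT1.61 and CT0.85. The other 7 peaked between CT9.46 and CT17.75, among them the rod channel subunits CNGB1 (52.4 ± 4.46 CPM at CT0, 150 ± 11.8 CPM at CT12) and CNGA1, the cone opsin PRA1 at CT11.7 and PDE6G at CT17.75. At night 1 cone gene was higher, PDE6C, and 1 lower, ARR3 (1 and 3 adjusted over the list alone), and 1 rod gene was higher and 2 lower (2 and 6 adjusted over the list alone), GUCA1A not with both tissues in 1 fit (edgeR adjusted p = 0.123). The PDE6C difference was -0.059 with CT12 counted as night and CT0 as day. Its call also ended with both tissues in 1 fit (edgeR adjusted p = 0.433) and without any 1 of 14 of the 18 libraries (edgeR adjusted p = 0.0509 to 0.111). Both lists were lower as a whole, with medians of -0.07 for cone (camera adjusted p = 0.00206; adjusted p = 0.253 with an estimated correlation) and -0.14 for rod (camera adjusted p = 0.00135; adjusted p = 0.589 with an estimated correlation), so both calls are lost there.

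**Figure D5:**
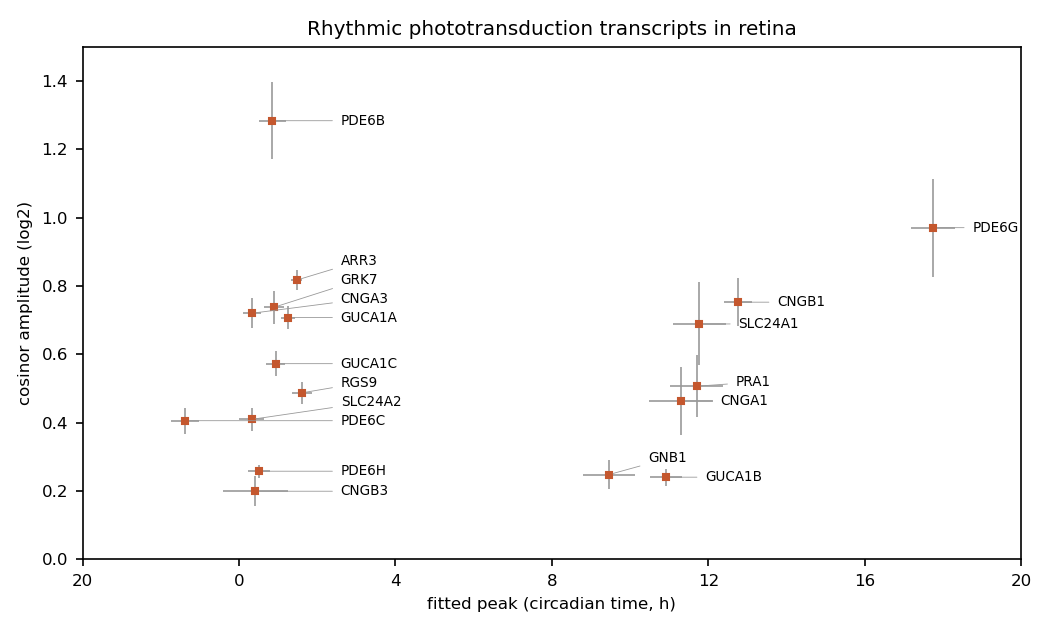
Fitted peak (circadian time, h) against amplitude (log2 units) of the 18 rhythmic phototransduction transcripts of the retina, with bars of 1 SE. Peaks fall into 11 transcripts from CT22.63 to CT1.61 and 7 from CT9.46 to CT17.75.

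In the remaining retina lists the share of rhythmic members ran from 0 to 44.4%, against 6.3% of all tested transcripts. Of cholesterol synthesis 4 of 16 were rhythmic (10 adjusted over the list alone), with a mean peak at CT15.03, among them NSDHL (amplitude 0.35 ± 0.06). At night none passed (6 higher adjusted over the list alone), with a median of 0.16 (camera adjusted p = 1.4e-08; adjusted p = 0.253 with an estimated correlation, which ends the call). Of glycolysis 5 of 16 were rhythmic (11 adjusted over the list alone), among them LDHB with its peak at CT2.39, and none passed at night (9 lower adjusted over the list alone), with a median of -0.10 (camera adjusted p = 1.9e-07; adjusted p = 0.253 with an estimated correlation, which ends the call). Of the pigment epithelium and visual cycle list 3 of 16 were rhythmic (3 adjusted over the list alone): MITF, ABCA4 and LRAT, the retinol esterifying enzyme, which fell at night by 1.25 ± 0.19 in 6 of 6 libraries. Its median was -0.27 (camera adjusted p = 0.00135; adjusted p = 0.589 with an estimated correlation, which ends the call). Medians of 0.05 for the unfolded protein response, with XBP1 rhythmic among its 14, -0.19 for choroid plexus markers (0 of 7) and 0.04 for ribosomal proteins (0 of 65) passed camera (adjusted p = 0.0163, 0.0229 and 4.5e-05), and none held with an estimated correlation (adjusted p = 0.538, 0.309 and 0.628). TYRP1 of the visual cycle list varied between retina libraries, from 51.8 CPM in CT20 replicate 2 to 276 CPM in CT0 replicate 3. CLIC6 of the choroid plexus list was at 24.8 and 77.9 CPM in the same libraries. Whether the medians of both lists reflect tissue content was not tested. Rhythmic counts elsewhere were 4 of 9 transcription factors, 2 of 7 opsins, 2 of 8 dopamine genes (DRD4 and DRD1), 2 of 15 amacrine and horizontal markers, 1 of 7 immediate early genes (EGR1) and 1 of 20 adrenergic genes. The rhythms of LHX4, RXRG, NEUROD1, OPN3, CALB1, SLC6A9, HK2, ENO2, GPI, SC4MOL, INSIG1, LSS, XBP1, DRD1 and EGR1 were each not called under at least 1 alternative, LSS also with the replicate number as a block (edgeR adjusted p = 0.0694). No member was called among 13 heat shock, 15 cell division, 12 mitochondrially encoded, 10 Müller glia, 9 ganglion cell, 7 bipolar cell, 6 endothelium, 6 neurosteroid, 5 myelin, 5 macrophage, 5 fibroblast, 4 lymphocyte, 3 blood cell, 3 lens and 3 striated muscle genes tested. Adjusted over the list alone, opsins had 5, amacrine markers 3, ganglion 3, and bipolar, endothelium and lymphocytes 1 each. Of the 12 W chromosome genes 2 were found and neither had the counts to be tested.

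Few retina transcripts passed the test of night against day. Of the 941 rhythmic ones, 320 peaked nearest CT0 and 329 nearest CT12, and for curves peaking at those times the contrast cancels out. The few calls thus do not show that levels changed little over the day. RDH8 fell at night by 1.90 ± 0.15 and LRAT by 1.25 ± 0.19, and PDE6G rose by 1.66 ± 0.22, each in 6 of 6 libraries. TPH1 rose by 1.01 ± 0.17 and AANAT by 0.40 ± 0.05, in 6 and 5 of 6 libraries. Among clock genes NR1D2, CRY2 and PER3 rose by 0.56 ± 0.05, 0.29 ± 0.03 and 0.49 ± 0.08, while PER2, CRY1, ARNTL and NFIL3 fell by 0.60 ± 0.07, 0.49 ± 0.05, 0.43 ± 0.06 and 0.64 ± 0.08. BLIMP-1 fell by 0.89 ± 0.08, ARR3 by 0.53 ± 0.05 and RGS9 by 0.35 ± 0.06. The repressor list, with 3 higher and 2 lower (4 and 2 adjusted over the list alone), did not pass as a list (camera adjusted p = 0.092, median 0.29). In all 42 transcripts were higher and 72 lower at night, of 14956 tested, and 109 of these 114 were rhythmic. These counts are small and moved with the method: DESeq2 called 101 and 185, transcripts summed per symbol gave 66 and 121, and CT12 as night with CT0 as day gave 155 and 215. The first count was 27 without CT20 replicate 1, 25 without CT8 replicate 2, 25 without CT16 replicate 2 and 23 without CT20 replicate 2.

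The tissues were then compared in their rhythms. Among 14281 transcripts tested in both, 549 were rhythmic in both, against 206 by chance (odds ratio 6.09, Fisher's exact test, one-sided p = 6.2e-143 over transcripts, which are not independent), or 60.5% of those rhythmic in the retina. With time as a 6-level factor 312 were rhythmic in both. Peaks lay within 4 h of each other in 412 of the 549, where chance gives 33.3%. The pineal peak was later by a median of 1.31 h, and the amplitude was larger in the pineal gland in 422. ARNTL, PER2, PER3, CRY1, NR1D2 and TPH1 were rhythmic in both. A direct test of the difference between rhythms called 2029 of 16831 transcripts, 1739 with the larger amplitude in the pineal gland and 290 in the retina. GNB3 came first: its amplitude was 1.52 in the pineal gland, with its peak at CT17.99, and 0.08 in the retina (edgeR adjusted p = 2.9e-17). G0S2 (3.19 and 0.64), PLEKHA6 (1.04 and 0.20), TMEM38A (1.06 and 0.30), SH3GLB2 (1.15 and 0.26) and FRMD4A (0.76 and 0.17) also had the larger amplitude in the pineal gland. So did PER3 (2.35 and 0.99) and CRY1 (1.02 and 0.32). SLC6A9, a glycine transporter, peaked at CT14.39 in the pineal gland and at CT23.94 in the retina, with amplitudes of 1.16 and 0.17. The kinase gene NIM1 (0.21 and 0.87) and NR2E3 (0.09 and 1.57) had the larger amplitude in the retina. TPH1 did not differ past the threshold (edgeR adjusted p = 0.568, amplitudes 1.08 and 0.90). By list, rhythms differed in 7 of 7 repressors, 7 of 12 melatonin, 8 of 10 cone (9 adjusted over the list alone), 5 of 13 rod, 12 of 14 unfolded protein, 8 of 13 heat shock (11), 9 of 16 cholesterol (14) and 6 of 16 glycolysis genes (9). Of the heat shock genes, CIRBP and HSPE1 were not called with time as a 6-level factor (edgeR adjusted p = 0.106 and 0.127), nor HSPA8 without either of 2 libraries (0.0517 and 0.0574).

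Levels in the pineal gland and retina were compared over all times, with 18 libraries each. TPH1 was at 19447 ± 8981 CPM in the pineal gland and 88.1 ± 43 CPM in the retina (SD, n = 18), ASMT was higher in the pineal gland by 5.61 ± 0.06, and OPNP was at 570 ± 135 and 1.07 ± 0.51 CPM. PRPH2, a rim protein of photoreceptor discs, was at 823 ± 53.7 CPM in the retina and 1.05 ± 0.365 CPM in the pineal gland. Of 16831 transcripts, 7264 (43.2%) were higher in the pineal gland and 6654 (39.5%) in the retina, with 2228 and 1432 of them at least 4-fold apart. All 18 libraries of the higher tissue lay above all 18 of the other in 3668 and 3388 transcripts (chance 2.2e-08%). The share of calls higher in the pineal gland was 52.2%, 52.9% with size factors or DESeq2, and between 61.9 and 62.7% with limma on log2 FPKM. The median log2 difference of all transcripts was 0.04, 0.05 with size factors or DESeq2 and between 0.19 and 0.23 with limma on log2 FPKM, so smaller list medians are to be read against that range. The largest pineal excesses were those of the matrix genes DCN (log2 11.49 ± 0.20), TINAGL1 (11.41 ± 0.26) and POSTN (10.91 ± 0.27), KCNQ1 (10.42 ± 0.23) and TENP (9.29 ± 0.15). KL, FOXC2 and IRF-4 had 0 counts in the retina and were at least 1689, 931 and 467-fold higher, set against 3 counts over its 18 libraries. CD4 had 3 counts in the retina and 3322 in the pineal gland, a ratio of 941 (95% exact interval 322 to 4565). In the other direction stood the acetylcholine receptor subunit CHRNB3 (-10.06 ± 0.07), LRTM1 (-10.05 ± 0.14), the homeobox gene SOHO-1 (-9.74 ± 0.14), GUCA1B (-9.66 ± 0.12), GYS2 (-9.62 ± 0.17), PRPH2 (-9.61 ± 0.06) and PRA1 (-9.59 ± 0.10). TM4SF4 and TBX5, with 0 pineal counts, were at least 1058 and 880-fold higher in the retina, and HMX1, with 2 pineal counts and 2447 in the retina, had a ratio of 1440 (398 to 11895). These intervals and floors cover counting error only.

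By list, 10 of 12 melatonin genes were higher in the pineal gland and 2 in the retina (median 2.50, camera adjusted p = 0.00166; adjusted p = 0.0973 with an estimated correlation, which ends the call), MEL1A being lower in the pineal gland at -6.35. Counts adjusted over the list alone were the same as those over all transcripts in every list of this comparison. All 14 lymphocyte markers (median 5.87, the same with CD8A set at its bound), 8 macrophage, 8 fibroblast and 4 blood cell markers were higher in the pineal gland, as were 9 of 11 endothelium, 15 of 17 cell division, 13 of 14 unfolded protein, 11 of 13 heat shock, 62 of 65 ribosomal, 11 of 12 mitochondrially encoded and 8 of 9 choroid plexus genes (median 1.93, the same with KL at its bound). BLB1, which presents antigen, was at 398 ± 134 and 2.88 ± 0.808 CPM, CD3E of T cells at 63.2 ± 26.7 and 0.235 ± 0.214 CPM, and COL3A1 of fibroblasts at 1092 ± 127 and 6.99 ± 2.95 CPM. Medians were 3.83 for macrophages, 7.67 for fibroblasts, 5.96 for endothelium, 2.03 for cell division, 0.96 for unfolded protein, 0.41 for heat shock, 0.46 for ribosomal and 0.29 for mitochondrially encoded. Camera adjusted p were 1.1e-05 for lymphocytes, 8.2e-04 for macrophages, 1.5e-04 for fibroblasts, 0.0158 for endothelium, 4.8e-04 for cell division, 2.1e-04 for unfolded protein, 0.0372 for heat shock, 6.3e-10 for ribosomal, 0.0204 for mitochondrially encoded and 0.0200 for choroid plexus. With an estimated correlation fibroblasts held (adjusted p = 0.0331), and the others did not (adjusted p = 0.0973 for lymphocytes, macrophages and cell division, 0.276 for endothelium, 0.122 for unfolded protein, 0.442 for heat shock, 0.264 for ribosomal, 0.481 for mitochondrially encoded and 0.311 for choroid plexus). In the retina all 10 cone, 15 amacrine and horizontal, 9 ganglion cell, 16 glycolysis and 7 repressor genes were higher, with 10 of 13 rod, 6 of 7 bipolar, 7 of 8 dopamine and 11 of 16 visual cycle genes. PAX6 of amacrine cells was at 360 ± 23.3 CPM in the retina and 6.18 ± 3.01 CPM in the pineal gland, and ENO1 of glycolysis at 4549 ± 212 and 932 ± 93.4 CPM. Camera adjusted p were 6.3e-06 for cone (median -4.84), 4.2e-07 for amacrine (-5.39), 2.1e-04 for ganglion cells (-2.95), 1.9e-08 for glycolysis (-2.26), 0.00182 for repressors (-1.19), 0.00123 for rod (-4.05), 0.00433 for bipolar (-3.40), 0.00438 for dopamine (-4.73) and 0.0276 for visual cycle genes (-0.80). Cone, bipolar, glycolysis and dopamine genes (adjusted p = 0.0331 each) and ganglion cells (0.0352) held with an estimated correlation, and amacrine (adjusted p = 0.0527), repressors (0.0973), rod (0.166) and visual cycle (0.378) did not. Lists that did not pass were activators (1 higher in the pineal gland and 5 in the retina), output (1 and 5), adrenergic (8 and 11), opsins (3 and 4), transcription factors (7 and 3), Müller glia (4 and 5), myelin (3 and 3), lens (3 and 1), striated muscle (4 and 2), immediate early (3 and 4), cholesterol (5 and 10) and neurosteroid (4 and 3). The opsin median was -0.74 and its mean 0.49. Rhythm lists whose night minus day median and test had opposite signs were, in the pineal gland, adrenergic, cone, visual cycle, Müller glia, endothelium, cell division and mitochondrially encoded genes, and in the retina output, melatonin, amacrine, endothelium and immediate early genes, none of them called.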

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

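The drift tests and those of regrouped libraries were set before their results were seen, while the tests on TTR and on retinal phototransduction were chosen, and their limits set, after the values had been seen.

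A difference between the tissues drew attention: the test of rhythm by tissue called 2029 transcripts. The smallest adjusted p-values were those of GNB3 (edgeR adjusted p = 2.9e-17, amplitude 1.52 in the pineal gland and 0.08 in the retina), G0S2 (3.2e-14, 3.19 and 0.64), PLEKHA6 (5.1e-14, 1.04 and 0.20), TMEM38A (5.3e-14, 1.06 and 0.30), SLC6A9 (1.0e-13, 1.16 and 0.17), PER3 (2.1e-13, 2.35 and 0.99), SH3GLB2 (2.8e-13, 1.15 and 0.26), CRY1 (4.5e-13, 1.02 and 0.32), NIM1 (4.8e-12, 0.21 and 0.87) and FRMD4A (7.2e-12, 0.76 and 0.17).

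Libraries were reassigned at random to ask whether chance groupings of the samples could give such counts, with the real grouping included among those counted. In each comparison 1 grouping, the real one, reached its count, so such counts are unlikely to arise by chance assignment. The number of groupings sets the limit: a share under 1 of 100, or 1 of 60 for the tissues, could not be shown. Regrouping also cannot tell time of day from other differences between samples that happened to fall with time. With 100 groupings each, the real count and the highest other were 3393 and 219 for pineal rhythms, 941 and 2 for retina rhythms, 2029 and 52 for the rhythm difference, 2413 and 1 for pineal night against day and 114 and 55 for retina night against day. With 60 groupings they were 13918 and 0 for the tissues.

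Rhythms were sampled over a single cycle in darkness, so a steady drift over the hours may look like part of a 24 h curve. Among transcripts called by a test of the 6 times, a straight line fitted better than the 24 h curve in 25.6% (711 of 2772) of pineal and 2.7% (14 of 515) of retina ones, both below the 50% set for drift as the main cause. These values argue against drift as the whole source of either set. Drift stays open for single transcripts among the 652 of 3393 pineal and 26 of 941 retina rhythmic ones that a line fitted better. A rhythm of the tissue itself over more than 1 cycle was not tested.

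TTR was between 982 and 1512 CPM in 3 pineal libraries and between 23013 and 43683 CPM in the other 15. The tables argue against time of day, since the highest TTR level at CT12 was 24.6 times the lowest among its 3 libraries, and against a mislabelled tissue, since TPH1, ASMT and OPNP in the 3 were at least 1.14 times the lowest of the other 15. Choroid plexus tissue missing from those pools stays open. Of the 8 other members of the list, 4 (KCNJ13, FOLR1, CLIC6 and KL) were lower in all 3 than in all 15 others. AQP1, FOXJ1, OTX2 and CA2 were not, which lies between the limits set for either answer. OTX2 is also in the list of photoreceptor and pineal transcription factors, so it need not follow choroid plexus tissue. CA2 was at 61.4 to 112 CPM in the 3, and of the other 15 only CT0 replicate 3, at 72.6 CPM, was not above that range. Time of day is the sole biological explanation that the labels give.

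Retinal phototransduction genes were rhythmic in 18 of 23 tested members. A share of photoreceptors that differed between libraries might move all of them alike, but 7 of the 18 peaked over 6 h from the mean peak of the rest, which argues against a common share as the whole source. Those 7 are mostly of the rod list and the other 11 mostly of the cone list, so shares of rods and cones moving apart stay open. PDE6B, GUCA1A and RGS9 of the rod list (CT0.85, CT1.26 and CT1.61) and PRA1 of the cone list (CT11.7) went with the other list. Membership of a list does not show in which of these cells a gene was expressed. Of the 23, a test of the 6 times, which does not assume a 24 h curve, called 17, and a straight line fitted better than that curve in 0.0% of these, which argues against drift as their main cause. Circadian control of these genes is a hypothesis found and tested on the same data.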

How the results depend on the processing

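All alternatives were chosen before the data were examined except the one that leaves out the 3 pineal libraries low in TTR. Counts within 1.5 times those reported were found throughout for pineal rhythms (2772 to 4093 over other settings, 3048 to 3394 with 1 library left out), tissue levels (6231 to 9853 and 5500 to 6968, and 7195 to 7305 and 6655 to 6780 with 1 left out), pineal night differences (1139 to 1707 and 896 to 1515) and the rhythm difference (1562 to 2326, and 1871 to 2138 with 1 left out). Retina rhythms came to at most 924 and stayed within 1.5 times of 941 with 1 library left out, pineal genes higher at night from 1114 to 1374 and lower from 862 to 1115, retina genes higher from 23 to 43 (27 without CT20 replicate 1, 25 without CT8 replicate 2, 25 without CT16 replicate 2 and 23 without CT20 replicate 2) and lower from 50 to 81, and those rhythmic in both tissues from 460 to 550 with 1 library left out, and called lists from 9 to 14 (pineal), 6 to 9 (retina) and 20 to 20 (tissues). Time as a 6-level factor lowered retina rhythms to 515 and those in both tissues to 312; it tests 5 coefficients in place of 2. Retina genes higher and lower at night became 101 and 185 with DESeq2 and 66 and 121 with transcripts summed per symbol. They became 155 and 215 with CT12 as night and CT0 as day. That contrast, unlike the main one, does not cancel out for peaks at CT0 and CT12, the times nearest most retina peaks. What caused the changes was not tested. With an estimated correlation 3 lists were called in the pineal gland, 0 in the retina and 6 between tissues. With CT12, CT16 and CT20 against CT0, CT4 and CT8 the night difference reversed for OPNP in the pineal gland (0.17, edgeR adjusted p = 0.068) and for PDE6C in the retina (-0.059, edgeR adjusted p = 0.67). With the replicate number as a block the counts were 3365 and 897 rhythmic, 1353 and 1089 pineal, 37 and 65 retina, 533 in both, 2047 for the difference, 7270 and 6652 for tissues and 13, 8 and 20 lists, none moved by over 1.5 times. Same-numbered libraries were weakly alike on average, though some pineal pairs were more so. With each group's mean removed, correlations of same-numbered libraries ran from -0.0961 to 0.407 over 45 pineal pairs (9 over 0.1). They ran from -0.114 to 0.0938 over 45 retina pairs (0 over 0.1). Over 18 pairs of pineal gland and retina they ran from -0.0805 to 0.161 (1 over 0.1). Means were 0.0379, 0.00125 and 0.0235, and -0.019, -0.000595 and -0.00136 for libraries of other numbers. The latter are no separate baseline, since removing each group's mean ties them to the former. A link between some pineal libraries of the same number is not excluded. Without the 3 libraries low in TTR, 2991 pineal transcripts were rhythmic, 2698 of them among the 3393. Leaving out 1 library ended the call of 9 of 97 named pineal rhythms, among them CSNK1E, 7 of 54 in the retina, among them EGR1, 9 of 66 and 2 of 10 night differences, 9 of 68 rhythm differences and 0 of 136 tissue differences. Depth limits what can be called for low transcripts: pineal MEL1A and the W chromosome genes had too few counts to be tested. Simulated rhythms of amplitude 0.25, in transcripts picked at random, were found in 40.3% of pineal and 35.8% of retina cases.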

Other observations

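No test was chosen for the values below, which were picked after they had been seen.

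A myelin gene and an interneuron gene stood high in a few pineal libraries. MBP, a myelin protein, was at 208 CPM in CT12 replicate 1, 371 CPM in CT20 replicate 1 and 94.3 CPM in CT0 replicate 2, and between 14.6 and 46.2 CPM in the other 15. GAD67, an enzyme of GABA synthesis, was at 21.2, 35.1 and 21.8 CPM in the same libraries and between 2.4 and 8.5 CPM in the others. CT12 replicate 3, which like the first pair was low in TTR, had 24.5 CPM of MBP.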
